A study of Aliger gigas with 7 samples.

How the data were processed

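Messenger RNA from the digestive gland of 7 wild adult female queen conch was measured on 1-colour (Cy3) oligonucleotide arrays, 8 arrays on 1 slide. Per the labels, 3 animals came from nearshore sites (NF2, NF3 and NM3) and 4 from offshore sites (OF1, OF2, OF3 and OF4), and NF3 was put on 2 arrays. The label description of OF4 calls it a technical replicate of NF3, against its own title, its location and the stated design, so OF4 was kept as an offshore animal and its similarity to NF3 was checked on the arrays.

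Per the file headers, the scanner files hold spot intensity as Agilent Feature Extraction 10.1.1.1 wrote it, with the background subtracted and the signal detrended within each array but not normalized between arrays. The authors also deposited a table of log2 values for 4328 gene titles in the 7 animals, with 1 missing value. How the authors normalized that table, merged probes under a title and assigned the titles is not stated. The scale of the table was checked on 1000 titles against scanner values after quantile normalization. For each title the nearest of the 15208 non-control probes was picked, at a median log2 distance of 0.0589. Slopes per animal, fitted only on titles nearer than that median, ran from 0.991 to 1.01. Picking the nearest probes makes both values close in advance, so they do not establish the scale. The detection level used below was taken from scanner signal before normalization and assumes like scales.

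The scanner files name no genes, so probes and titles were analysed separately. For the probes, the processed intensity was taken to log2 and each array's 75th percentile over its 15208 non-control probes was subtracted, flagged spots were left out, and the 2 arrays of NF3 were averaged. A probe was tested where it was well above background in at least 3 of the 7 animals, which left 11280 probes. For the titles, the authors' table was used as deposited and all 4328 titles were tested. The gene lists and the named genes had been planned on the probes and were moved to the titles for want of a probe annotation.

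Nearshore and offshore animals were compared with limma 3.58.1 in R 4.3.3, with lmFit, location as the only term and eBayes without trend or robust fitting, 2-sided, and with Benjamini-Hochberg adjustment over all probes or all titles tested. An adjusted p under 0.05 was called. A title whose mean lay under a log2 detection level of 3.01, the mean over the arrays of the lowest signal well above background, was given no fold in that group, and the fold was set as a bound with the values of that group under the level raised to it. Such a bound holds for that mean level only. The level of single arrays ran from 2.79 (OF2) to 3.51 (NF2), and a higher level gives a smaller bound. Values of the other group under the level were kept as measured. The offshore group was the reference, and every log2 difference is nearshore minus offshore. The animals carry numbers in the labels, and these were not used as pairs. With 3 and 4 animals, their number limits the precision.

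The 22 gene lists were written as text patterns before the data were examined, as were the tests, the grouping and most of the alternatives. They cover ribosomal proteins, translation factors, the respiratory chain, glycolysis and gluconeogenesis, chaperones, antioxidant enzymes, xenobiotic metabolism, metal handling, carbohydrases, proteases and lipases, lipid metabolism, proteasome and ubiquitin, the secretory pathway, histones and cell cycle, nuclear receptors and steroid enzymes, and the cytoskeleton. A further 6 lists mark other tissues or food: immune cells, ovary and female tract, testis and sperm, muscle, nervous tissue, and algal plastids. Each list of at least 5 titles was tested with camera of limma at an inter-gene correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. Patterns match words in a title, so a list can hold a title that belongs elsewhere.

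Genes were named by a rule set with the lists: the 12 largest rises and the 12 largest falls among called titles with an informative name whose groups did not overlap, and up to 4 members of smallest p in each list. Of the called titles, 5 had no informative name. The fits were tested on simulated data with 200 changed features in 20 simulations, with independent normal noise for each feature. Under such noise the adjustment holds the false share near 5% by design, so it is not the error rate of the real calls. Of the changed titles, 38.3% were recovered at a log2 difference of 1, 79.7% at 2 and 93.6% at 3, with 5.00% false among those called. For probes the shares were 17.2%, 67.1% and 83.0%, with 5.21% false. A simulated list of 76 independent titles was called in 100% of runs at a shift of 0.25.

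The alternatives for the probes were quantile normalization, the array median, normexp with an offset of 50 followed by quantile normalization, no filter, a filter over all 7 animals, flagged spots kept, and the first array of NF3 alone. Further ones were the row on the slide as a covariate, the label number as a block, trend with robust fitting, array weights, and each animal left out. For the titles, quantile normalization of the table, subtraction of column medians and a minimum level were added after the table had been seen, as were the fits without NF2 and OF1 and without the 250 catalogue probes. Pairs of arrays were compared by Pearson correlation and median absolute log2 difference over the tested probes, without a test. The 536 control spots of each array were left out.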

Results

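Gene expression was measured in the digestive gland of queen conch, a large marine snail, taken as adult females from nearshore and offshore sites in the Florida Keys. Per the labels, reproduction was normal offshore and impaired nearshore, and the nearshore female NM3 had apparent imposex, the growth of male organs on a female. There were 3 nearshore animals (NF2, NF3 and NM3) and 4 offshore animals (OF1, OF2, OF3 and OF4), each on 1 array except NF3, which was on 2. Of the 15208 non-control probes per array, between 66.4% (OF3) and 77.6% (NF2) were well above background, and no spot was saturated. The same held for 26.4% (OF1) to 43.2% (NF2) of the 250 catalogue probes, those outside the 14958 of the conch design. The flag thus also passes probes not made for conch. The lowest log2 signal that passed ran from 2.79 (OF2) to 3.51 (NF2). The comparison asked which transcripts of the gland differ between animals of the nearshore sites and those of the offshore reference.

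Vitellogenin 2, whose name is that of a precursor of egg yolk protein, showed the largest difference of all 4328 gene titles. Its log2 level was 6.97 ± 1.39 (SD, n = 3) nearshore and 15.77 ± 1.97 (SD, n = 4) offshore, a difference of -8.80 (SE 1.09), or 446-fold lower nearshore with an adjusted p of 0.0174. Amylase, Alpha 1A; Salivary, a starch-digesting enzyme, was 6.87-fold lower nearshore, at 14.61 ± 0.10 (SD, n = 3) against 17.39 ± 0.42 (SD, n = 4), with an adjusted p of 0.00805. Both titles of the sterol-synthesis enzyme lanosterol demethylase were lower to a like degree. Cytochrome P450, Family 51 differed by -2.72 (SE 0.26) and Cytochrome P450, Family 51, Subfamily A, Polypeptide 1 by -2.76 (SE 0.28), each with an adjusted p of 0.00805. Farnesyl Diphosphate Synthase, an enzyme upstream in the same route, differed by -2.11 (SE 0.28, adjusted p 0.0181), while Farnesyl Pyrophosphate Synthase, a further title of that enzyme named after its values were seen, stood at -0.61 and was not called (adjusted p 0.361). Adenosylhomocysteinase, which breaks down the by-product of methylation reactions, fell from 13.47 ± 0.23 (SD, n = 4) offshore to 10.81 ± 0.08 (SD, n = 3) nearshore and had the smallest adjusted p, 0.00381. Similar To Protein Tyrosine Phosphatase, Receptor Type, K Precursor differed by -2.17 (SE 0.22, adjusted p 0.00805), and Phenylalkylamine Ca2+ Antagonist Binding Protein by -2.38 (SE 0.36, adjusted p 0.0318). The other 4 of the 12 largest falls that the naming rule picked had nearshore means under the detection level: 50S Ribosomal Protein L18 was at least 2.14-fold lower, Double C2, Beta at least 1.43-fold lower, and a pair of clone-named titles at least 5.41-fold and 12.7-fold lower. Hypothetical Protein LOC575598, which the rule left out for its name, differed by -4.29 (SE 0.56, adjusted p 0.0181).

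Many calls among these falls were lost when 1 animal was left out. The differences kept their direction, which groups that do not overlap fix in advance. Without NF3, adjusted p was 0.0505 for Vitellogenin 2, Amylase, Cytochrome P450, Family 51, Adenosylhomocysteinase and the phosphatase-like title, 0.0508 for the Subfamily A title of Cytochrome P450, Family 51, and 0.0905 for Farnesyl Diphosphate Synthase. Without NM3 it was 0.0930 for Vitellogenin 2 and Farnesyl Diphosphate Synthase, 0.0562 for Amylase, 0.0566 and 0.0585 for the Cytochrome P450 titles and 0.0585 for the phosphatase-like title, while Adenosylhomocysteinase stayed called. Without NF2, Vitellogenin 2 had 0.0526. Phenylalkylamine Ca2+ Antagonist Binding Protein was called only without OF2 or OF3, and without NF2, NF3, NM3, OF1 or OF4 its adjusted p lay between 0.0605 and 0.111. Among the falls given as bounds, 50S Ribosomal Protein L18 lost its call without any animal but NF2 (0.0605 to 0.115), and Double C2, Beta without NF2, NF3, NM3, OF1 or OF2 (0.0519 to 0.111). The clone-named title at least 12.7-fold lower lost it without the same 5 animals (0.0605 to 0.1002), and the one at least 5.41-fold lower without NF3 (0.0505). Over all 15 alternatives, the difference of Vitellogenin 2 ran from -9.57 to -7.44 (adjusted p 0.00899 to 0.109), that of Amylase from -2.98 to -2.57 (0.00201 to 0.138), and that of Adenosylhomocysteinase from -2.75 to -2.58 (0.00101 to 0.118).

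T-cell Lymphoma Invasion And Metastasis 1, a name given to an activator of the Rac switch protein, had the largest rise of the called titles. It stood at 16.02 ± 1.00 (SD, n = 3) nearshore and 12.66 ± 0.20 (SD, n = 4) offshore, a difference of 3.36 (SE 0.43, adjusted p 0.0181). Sulfotransferase Family, Cytosolic, 1A, Phenol-preferring, Member 3, of a family that attaches sulfate to phenols, was 8.71-fold higher nearshore, at 11.71 ± 0.52 (SD, n = 3) against 8.59 ± 0.52 (SD, n = 4), with an adjusted p of 0.0132. Similar To Glutathione S-transferase Pi, of a family that joins glutathione to reactive compounds, was higher by 1.72 (SE 0.28, adjusted p 0.0367). A title similar to the beta subunit of voltage-gated potassium channels was higher by 2.31 (SE 0.26, adjusted p 0.0132), KIAA1826 Protein by 3.14 (SE 0.50, adjusted p 0.0367), and Carboxylic Ester Hydrolase by 1.76 (SE 0.30, adjusted p 0.0390). Offshore means under the detection level limited 4 of the 12 largest rises that the naming rule picked to bounds. A reverse transcriptase-like title was at least 5.51-fold higher, a helicase and ubiquitin ligase title at least 1.64-fold, Oxct1-prov Protein at least 1.23-fold, and an insect-named title at least 1.31-fold. The remaining pair carried clone names and was higher by 2.40 and 2.68. Hypothetical Protein LOC548944, which the rule left out for its name, differed by 3.33 (SE 0.64, adjusted p 0.0489).

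Calls among the rises were also lost when 1 animal was left out, while the differences stayed at 3.02 to 3.93 for T-cell Lymphoma Invasion And Metastasis 1, 2.15 to 2.52 for the potassium channel title and 1.52 to 2.05 for Similar To Glutathione S-transferase Pi. T-cell Lymphoma Invasion And Metastasis 1 had an adjusted p of 0.0793 without NF3, 0.0930 without NM3 and 0.0541 without OF2. The sulfotransferase had 0.0769 without NF3 and 0.0876 without NM3, and the potassium channel title had the same values plus 0.0530 without OF2. Similar To Glutathione S-transferase Pi lay between 0.0633 and 0.117 when NF3, NM3, OF1, OF2, OF3 or OF4 was left out. The reverse transcriptase-like title, the insect-named title and the clone-named title with a difference of 2.40 lost their calls without any of the 7 animals (0.0503 to 0.138). The clone-named title with 2.68 lost its call without any but NF2 (0.0826 to 0.143), and its difference ran from 2.29 to 3.34, highest without NF2. The helicase and ubiquitin ligase title lost it without NF3 or OF2 (0.0905 and 0.0541), and Oxct1-prov Protein without NF3, NM3 or OF2 (0.0505 to 0.0930). KIAA1826 Protein and Carboxylic Ester Hydrolase stayed called only without OF4, and without each other animal lay between 0.0530 and 0.124. Over all 15 alternatives the difference of the sulfotransferase ran from 2.90 to 3.42 (adjusted p 0.00209 to 0.148), and the adjusted p of T-cell Lymphoma Invasion And Metastasis 1 from 0.00209 to 0.147.

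**Figure D1:**
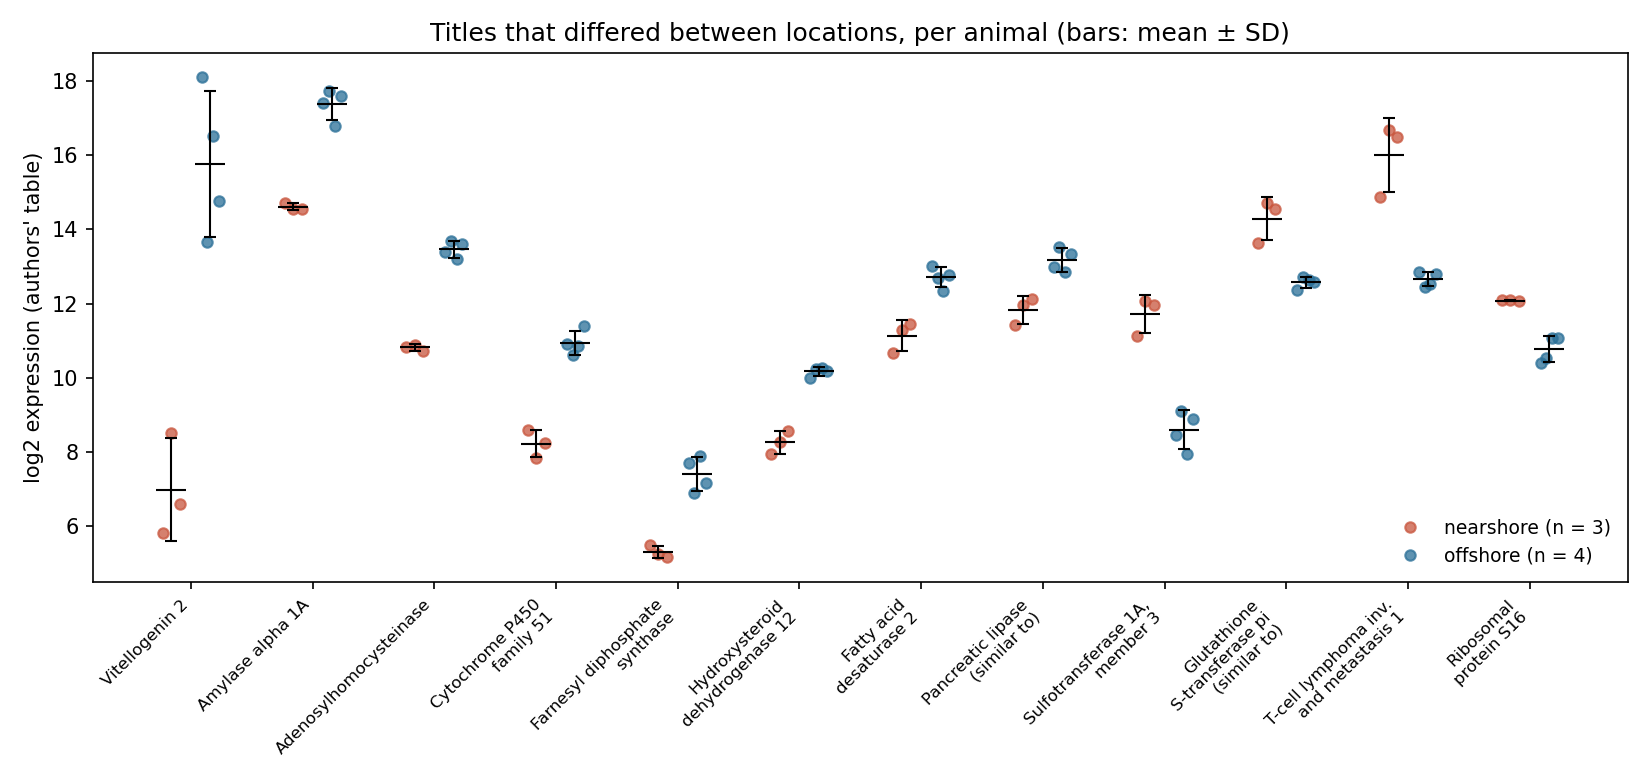
Log2 expression of 12 titles called between locations, in the authors' table, for each nearshore (n = 3) and offshore (n = 4) animal, with the mean and SD as bars. In each title no nearshore animal overlaps an offshore animal, and Vitellogenin 2 spans the widest gap, with means of 6.97 and 15.77.

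Across all titles, limma called 83 of 4328, of which 28 were higher and 55 lower nearshore. The median fold was 3.05, taken over all 83, also those with a mean under the detection level. At an unadjusted p under 0.05 there were 870, and 254 at an adjusted p under 0.1. All 83 had groups that did not overlap, as did 21.3% of all titles, where chance gives 5.71%. Leaving out any animal moved the count by more than 1.5 times: 36 titles without NF2, 0 without NF3, 4 without NM3, 35 without OF1, 11 without OF2, 43 without OF3 and 28 without OF4. With the row of the array on the slide as a covariate, 27 titles were called, and 0 with the label number as a block. With array weights it was 301, 139 higher and 162 lower.

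Among the scanner probes, which carry no gene names, 178 of 11280 were called, 77 higher and 101 lower nearshore, with a median fold of 3.48. At an unadjusted p under 0.05 there were 2467. All 178 had groups that did not overlap, as did 21.8% of tested probes, where chance gives 5.71%. The count was 0 without NF3, 23 without NM3, 98 without OF1, 62 without OF2 and 51 without OF4, and it was 134 without NF2 and 171 without OF3. It was 100 with the slide row as a covariate, 35 higher and 65 lower, and 1004 with array weights, where the majority turned to higher nearshore, 573 against 431.

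In the lists of lipid metabolism and of steroid enzymes, 3 titles were called, each lower nearshore. Among 47 titles of lipid metabolism, 0 rose and 2 fell in limma, and 9 had an unadjusted p under 0.05: Acyl-CoA Synthetase Long-chain Family Member 1, which activates fatty acids, differed by -1.64 (SE 0.25, adjusted p 0.0318), and Fatty Acid Desaturase 2 by -1.57 (SE 0.26, adjusted p 0.0367). Adjusted over the list alone, 2 rose and 4 fell, among them Fatty Acid Desaturase 1 (-1.26) downward and Carnitine Palmitoyltransferase 2 (1.40), which brings fatty acids into mitochondria, upward. Among 17 nuclear receptor and steroid enzyme titles, 1 fell, Hydroxysteroid Dehydrogenase 12 (-1.91, SE 0.20, adjusted p 0.0104), and 2 fell adjusted over the list alone. The other was NAD(P) Dependent Steroid Dehydrogenase-like, at least 1.36-fold lower with a nearshore mean under the detection level, while Steroid 5 Alpha-reductase 1 (-0.70) and Retinol Dehydrogenase 11 (0.83) did not pass. In the secretory list of 32 titles, Protein Disulfide Isomerase Associated 3 (-1.67, SE 0.25, adjusted p 0.0318) and Signal Sequence Receptor, Alpha (-1.08, SE 0.17, adjusted p 0.0334) fell, and 3 fell adjusted over the list alone. Its member 6-phosphofructo-2-kinase/fructose-2,6-biphosphatase 1 (-0.53) belongs to sugar metabolism and was caught by the text pattern. Hydroxysteroid Dehydrogenase 12 lost its call without NF3 (0.0701). Acyl-CoA Synthetase Long-chain Family Member 1 lost it without any animal but NF2 (0.0503 to 0.0978), Fatty Acid Desaturase 2 without any but OF3 (0.0682 to 0.111), Protein Disulfide Isomerase Associated 3 without any but NF2 or OF3 (0.0605 to 0.0930), and Signal Sequence Receptor, Alpha without any of the 7 (0.0544 to 0.115). Over all 15 alternatives these adjusted p-values ran from 0.00325 for Hydroxysteroid Dehydrogenase 12 to 0.165 for Fatty Acid Desaturase 2.

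Digestive enzymes called between locations were lower nearshore. Of 29 carbohydrases, Amylase, Alpha 1A; Salivary alone passed, and adjusted over the list alone Putative Cellulase also rose, with both of its means under the detection level. Chitinase 1 (-0.99) and Mannosidase, Endo-alpha-like (-1.50) did not pass. Of 42 proteases and lipases, Similar To Pancreatic Triglyceride Lipase fell, from 13.17 ± 0.31 (SD, n = 4) offshore to 11.83 ± 0.37 (SD, n = 3) nearshore, with an adjusted p of 0.0489. Adjusted over the list alone 3 fell, with Phospholipase D2 (-0.82) and Similar To Cathepsin L, A added, the latter at least 1.53-fold lower with a nearshore mean under the detection level. The lipase lost its call without any of the 7 animals (0.0633 to 0.130) and ran from 0.0165 to 0.207 over all 15 alternatives. Similar To Cathepsin L, A passed over all titles without OF4 (0.0433).

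The xenobiotic metabolism list held called risers that match its name, while the called fallers named here do not. Of 77 titles, 2 rose, 4 fell and 71 did not pass, and 3 rose and 7 fell adjusted over the list alone. The risers were the 1A sulfotransferase and Similar To Glutathione S-transferase Pi. The called fallers included both titles of Cytochrome P450, Family 51, an enzyme that makes sterols and does not clear foreign compounds, and Similar To Arylsulfatase B Precursor (-1.64, SE 0.23, adjusted p 0.0253), an enzyme of the lysosome. The other fallers are not described here, so these titles do not stand for all of them. The arylsulfatase lost its call without NF2, NF3, NM3, OF2 or OF4 (0.0507 to 0.1001) and ran from 0.00899 to 0.148 over all 15 alternatives. Of 27 antioxidant titles 0 passed in limma, 1 had an unadjusted p under 0.05, and the first in rank was Catalase (-0.93). Of 25 metal-handling titles 0 passed and 6 had an unadjusted p under 0.05, led by Ferritin, whose means both lay under the detection level, and Selenoprotein W, 1 (-1.16). The next in rank of that list were sugar transferases caught by their wording.

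Protein-making and protein-folding titles held few calls. Of 76 ribosomal proteins, Ribosomal Protein S16 rose by 1.31 (SE 0.23, adjusted p 0.0406) and 50S Ribosomal Protein L18, a bacterial or organelle type of protein, fell, and 74 did not pass. Adjusted over the list alone the counts were again 1 and 1, without Ribosomal Protein S26 (0.96) and Ribosomal Protein S10 (-1.27). Of 66 chaperones 0 passed in limma and 12 had an unadjusted p under 0.05, among them DnaJ Homolog, Subfamily A, Member 3A (0.94) and FK506 Binding Protein 2, 13kDa (-1.20). Of 79 proteasome and ubiquitin titles 2 rose, Proteasome 26S Subunit, Non-ATPase, 8 by 1.09 (SE 0.21, adjusted p 0.0490) and the helicase and ubiquitin ligase title, and the same number rose adjusted over the list alone. Of 66 translation factors 0 passed and 20 had an unadjusted p under 0.05, such as Elongation Factor 1 Homolog (-0.93). Ribosomal Protein S16 lost its call without any of the 7 animals (0.0542 to 0.130) and the proteasome subunit without any but OF3 (0.0975 to 0.147), while without NF2 RNA Binding / Translation Initiation Factor (1.92) passed at 0.0116 and Ubiquitin-conjugating Enzyme E2D 2 (-2.05) at 0.0306. Over all 15 alternatives Ribosomal Protein S16 ran from 0.0135 to 0.152.

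Energy, cell-cycle and structural lists held few calls. Of 90 respiratory chain titles 0 passed in limma and 11 had an unadjusted p under 0.05, and of 24 glycolysis and gluconeogenesis titles 0 passed and 3 did so, led by phosphoenolpyruvate carboxykinase (3.17, SE 0.83). Of 34 histone and cell-cycle titles 0 passed, 6 had an unadjusted p under 0.05, and 1 fell adjusted over the list alone, Cell Division Cycle 25C (-0.84). Of 60 cytoskeleton titles 1 rose, Kinesin-associated Protein 3, at least 2.68-fold (adjusted p 0.0419), also adjusted over the list alone. It lost its call without any of the 7 animals (0.0541 to 0.120) and ran from 0.0195 to 0.151 over all 15 alternatives. Profilin 1 (1.36) and Thymosin, Beta 10 (0.71) did not pass.

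Among the lists for other tissues and food, Vitellogenin 2 was the only called title. It belongs to the ovary and female tract list of 6 titles, whose other members included Egg Permeability Glycoprotein (0.47) and EGg Laying Defective, whose means both lay under the detection level, neither called. Of 56 testis and sperm titles 0 passed in limma and 6 had an unadjusted p under 0.05, and 2 fell adjusted over the list alone, Outer Dense Fiber Of Sperm Tails 3, at least 2.64-fold with a nearshore mean at the detection level, and Motile Sperm Domain Containing 2 (-0.81). No title passed among 29 immune, 26 muscle, 20 nervous and 7 algal plastid titles, where 4, 5, 3 and 1 had an unadjusted p under 0.05. Collectin Sub-family Member 11, an immune lectin, had a large but uneven difference of -5.12 (SE 1.64), Arginine Kinase stood at -0.49 and Synaptotagmin XV at -0.89. Fanconi Anemia, Complementation Group M and Similar To Plectin 1 Isoform 1, both with offshore means under the detection level, sit in the immune list by their wording. Photosystem II 47 KDa Protein had both means under the detection level.

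As whole lists, 0 of 22 passed camera, 5 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0639. Those 5 were ribosomal proteins (median 0.16, p 0.00433), chaperones (0.27, p 0.00581) and proteasome and ubiquitin (0.20, p 0.0446) toward higher, and carbohydrases (-0.21, p 0.0287) and xenobiotic metabolism (-0.14, p 0.0367) toward lower nearshore. Next were the nuclear receptor and steroid enzymes (-0.07, p 0.0568) and the proteases and lipases (-0.19, p 0.0667). With an estimated correlation none of these held, with 0 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.538. The directional test of fry, which asks whether titles move on balance to one side, gave 0 lists with a smallest adjusted p of 0.0849 and 8 at an unadjusted p under 0.05. Its mixed test, which asks for change to either side, gave 19, and neither compares a list with other titles. Camera p was 0.171 for the cytoskeleton (-0.11), 0.252 for the secretory list (0.01), 0.254 for testis and sperm (-0.03), 0.258 for metal handling (-0.06), 0.267 for antioxidants (-0.11) and 0.355 for histones and cell cycle (-0.06). It was 0.462 for translation factors (0.16), 0.480 for muscle (-0.15), 0.575 for the respiratory chain (0.09) and 0.664 for ovary and female tract (0.19). It was 0.812 for nervous tissue (0.10), 0.871 for immune titles (0.08), 0.873 for lipid metabolism (0.02), 0.910 for glycolysis and gluconeogenesis (-0.00) and 0.929 for algal plastids (-0.15). The ovary list had a positive median and a mean of -1.33 with camera toward lower, which Vitellogenin 2 made. Lipid metabolism (mean -0.04) and the secretory list (mean -0.08) also had a positive median with camera toward lower, immune titles had a mean of -0.14 with camera toward higher, and glycolysis a mean of 0.14 with camera toward lower. The medians of glycolysis and of algal plastids changed sign under another scaling of the table, at 0.03 with column medians subtracted and 0.06 with quantile normalization. Leaving out NF2 or OF3 let ribosomal proteins pass at 0.0246 and 0.0133, and leaving out NF3 let chaperones pass at 0.0167, each toward higher and at the preset correlation, and the smallest adjusted p over all list alternatives with camera ran from 0.00486 to 0.538.

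**Figure D2:**
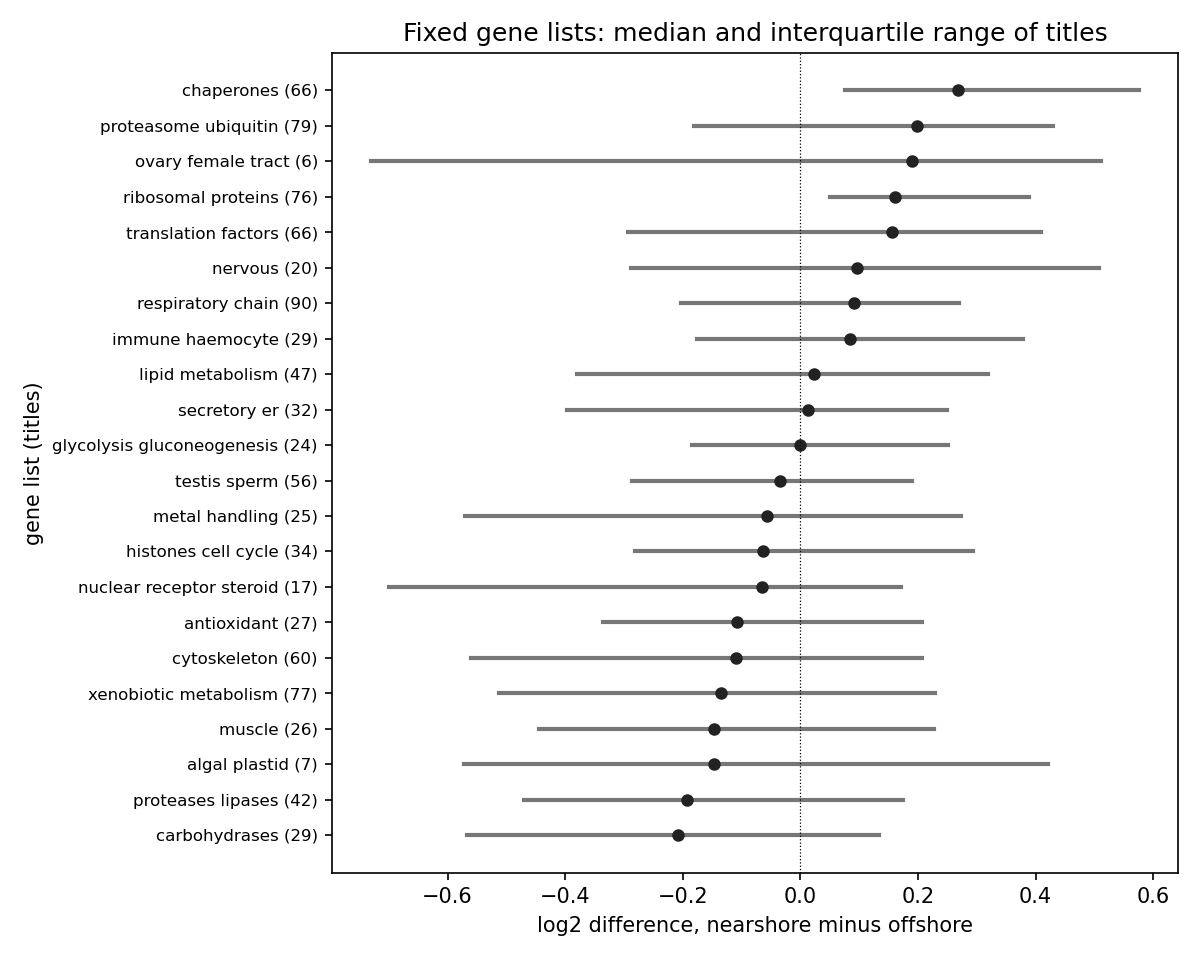
Median (point) and interquartile range (line) of the log2 differences, nearshore minus offshore, of the titles in each of 22 gene lists, with the number of titles in brackets. Medians run from -0.21 for carbohydrases to 0.27 for chaperones, and the algal plastid and glycolysis medians change sign under another scaling.

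Animals differed far more from each other than repeated arrays of the same animal did. Over the 11280 tested probes, the 2 arrays of NF3 had a correlation of 0.996 across probes and a median absolute log2 difference of 0.0985. Pairs of different nearshore animals differed by 0.232 to 0.429, pairs of offshore animals by 0.351 to 0.471 and pairs across locations by 0.430 to 0.567. Within the nearshore group NF3 and NM3 were the closest pair and NF2 stood apart from both. OF4 differed from NF3 by at least 0.439, more than the 2 arrays of NF3 did and within the range of pairs across locations. The main axis of variation, 35.1% of the variance of the probes, separated the locations, and the next, 19.7%, set NF2 and OF1 apart from the other animals of both locations.

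**Figure D3:**
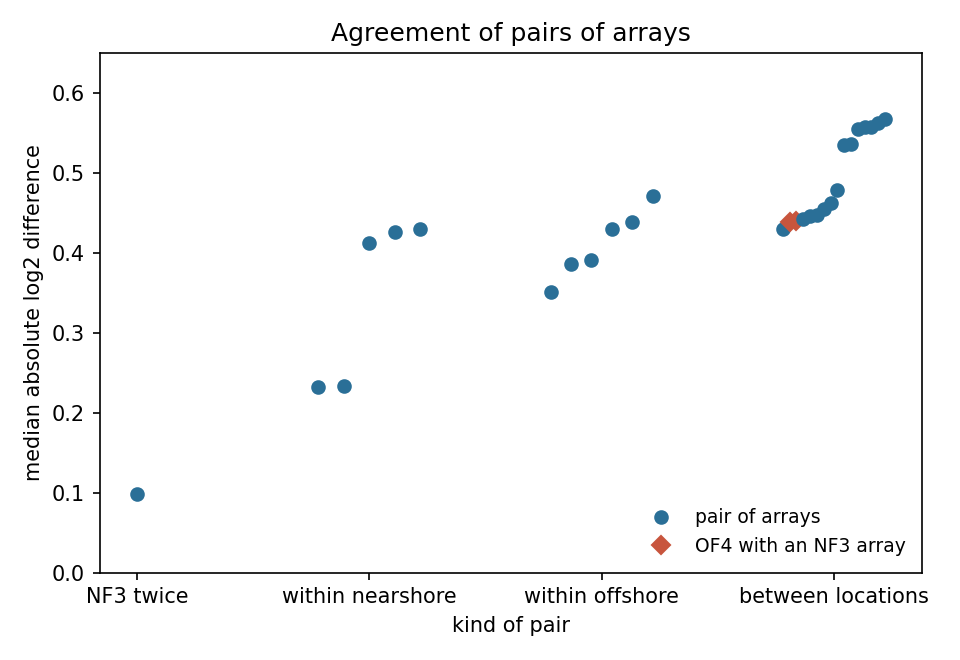
Median absolute log2 difference over tested probes for each pair of arrays, by kind of pair, with pairs of OF4 and NF3 as diamonds. The NF3 arrays differ by 0.0985, and OF4 differs from them by at least 0.439, within the range of 0.430 to 0.567 of pairs across locations.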

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

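The test for far-off values was set before its results were known, and no test was chosen afterwards in this part. In 105 named titles, the 4 offshore animals were searched for a single value whose gap to the nearest other, as a share of the range, exceeded Dixon's critical value, which chance gives in about 1 of 20 titles. It was found in 6 of 105, about what chance gives, so no pattern was weighed. In Cytochrome P450, Family 51, Subfamily A, Polypeptide 1, a sterol-synthesis enzyme called lower nearshore, OF4 stood at 10.60 with the other offshore animals at 9.64 to 9.78. In Oxct1-prov Protein, called higher nearshore, OF4 stood at 1.23 with the others at 1.52 to 1.54, all under the detection level of 3.01. In Elongation Factor 1 Homolog, OF3 stood at 9.10 with the others at 9.63 to 9.71. In ATPase, Ca++ Transporting, Cardiac Muscle, Fast Twitch 1, OF4 stood at 6.70 with the others at 6.25 to 6.31. In Ribulose-5-phosphate-3-epimerase, from the algal list, OF1 stood at 5.95 with the others at 6.78 to 6.80. In Synaptophysin-like Protein, OF2 stood at 1.59 with the others at 1.37 to 1.40, again under the detection level. In both called titles every offshore animal stayed on its own side of every nearshore animal.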

How the results depend on the processing

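All alternatives for the title count, the scalings and minimum level of the authors' table, and the fits without NF2 and OF1 and without the catalogue probes were chosen after the table had been seen. No named title changed direction under any alternative. For the 24 with the largest differences, whose groups did not overlap, leaving out animals could not have turned the direction. Trend and robust fitting leaves the difference itself unchanged for every title. Of the 24 named titles with the largest differences, the same call held for 24 with column medians subtracted and with array weights, 23 with quantile normalization and with trend and robust fitting, and all 20 left at or above the detection level. The row covariate kept 16, the fit without NF2 and OF1 kept 9, and the replicate block 0. Leaving out an animal kept 15 without NF2, 0 without NF3, 3 without NM3, 13 without OF1, 10 without OF2, 16 without OF3 and 17 without OF4. The probe count of 178 was 122 to 213 under other normalizations, filters, flags and the trend fit, but the probes called changed. Of the main 178, 150 stayed called with quantile normalization, 106 with normexp, 103 without the filter and 130 with the filter over all 7 animals. Between 159 and 178 stayed called with the array median, flagged spots kept, the first array of NF3 alone and the trend fit. It was 100 with the row covariate, 1004 with array weights (573 higher and 431 lower, the reverse of the main balance of 77 and 101), 0 with the replicate block and 83 in the authors' table, which holds fewer features. Leaving out animals gave 0 to 171 probes. The title count of 83 was 71 to 95 under 4 settings, where 64 to 81 of the main 83 stayed called. It was 27 with the row covariate, 301 with array weights, 0 with the replicate block and 26 without NF2 and OF1. When an animal was left out, it was 0 to 43. The block spends 3 of the degrees of freedom, and label numbers gave no steady sign of pairing. Across the tested probes, deviations of same-numbered animals correlated at -0.05, -0.15 and 0.21, and those of other pairs across locations at -0.16 to 0.18. Across titles this was not computed. Fewer animals also leave less to estimate the spread, but the cause of the loss without NF3 in particular was not tested. The cause was not tested for the row covariate or the array weights. For lists, 0 passed in the main test, with 1 (ribosomal proteins) under quantile normalization, 1 under trend and robust fitting, 1 under array weights, 1 (chaperones) under the replicate block, 19 in the mixed test of fry, and 0 to 1 when an animal was left out, again with the cause not tested. With an estimated correlation, run at the main setting alone, 0 passed and the smallest adjusted p was 0.538. The median difference of all probes moved from 0.12 to 0.01 with normexp. The agreement of arrays kept its values within the spread between pairs. Not run were an animal-as-random-block fit of all 8 arrays, since 1 repeated animal gives no estimate of the correlation, and the scanner-file alternatives for lists and named genes, since those files name no genes. Weak signal limits the 19 called titles with one mean under the detection level and the 3 with both under it.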

Other observations

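The tests on vitellogenin, on sterol synthesis and on axoneme titles, their added lists, and the count of splits for gene lists were all chosen after the results had been seen, and only the splits for probes and titles were set earlier. The bounds that decide the ovary, the remaining-sterol, the axoneme-signal and the sperm tests were also rewritten after their values were known: under the earlier bounds the ovary, signal and sperm explanations would have been argued against, and the sterol fall would have been put down to the called titles alone. Vitellogenin 2 was the most different title, and its 4 offshore values were far apart: 18.12 in OF1, 16.54 in OF3, 14.76 in OF4 and 13.65 in OF2, against 5.81 to 8.51 nearshore. Piwi-like 1, a germ-line name picked after its values were seen, had the same order offshore, with 11.03 in OF1, 8.24 in OF3, 5.47 in OF4 and 3.23 in OF2. Its nearshore values of 3.68 to 4.44 all lay above OF2, unlike those of Vitellogenin 2, and it was not called (difference -2.94, SE 1.62). With 4 animals this order was not tested.

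The location difference in probes and titles was larger than other splits of the animals gave. Of the 35 splits of 7 animals into 3 and 4, only 1, the real one, gave as many as 178 probes, and the highest other gave 5. For titles it was again 1 of 35, with 83 titles and 2 in the highest other. The real split thus ranked first for both, but a first rank among 35 splits cannot exclude chance. The other splits mix the locations, which adds to their spread and lowers their counts. The gap in counts is therefore no measure of evidence. For the gene lists the real split gave 0 and the highest other 2, so all 35 splits gave as many, which a count of 0 fixes in advance and which says nothing about chance.

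A candidate explanation for the vitellogenin difference is ovary tissue carried into the offshore glands at dissection. An added list of 14 oocyte titles, of which 6 are also in fixed lists, had a median difference of -0.060, with quartiles of -0.69 and 0.28. Its nearshore median of 6.72, above the 6.28 of all titles, is a baseline that would hide a small amount of ovary, so carried-over tissue cannot be told apart from a difference within the gland. The most abundant members were Cytoplasmic Polyadenylation Element Binding Protein 3 (7.93 nearshore, 8.99 offshore) and Cell Division Cycle 20 Homolog (8.49 and 8.11), and the 5 other titles of the fixed ovary list had a median of 0.47. That median decides nothing, since these titles were matched on words and EGg Laying Defective had both means under the detection level. Among 10000 random lists matched on level, the oocyte list lay at percentile 99.96 in OF1, 32.74 in OF3, 2.42 in OF2 and 0.55 in OF4, and at 98.37 in nearshore NF2. OF2 and OF4, where Vitellogenin 2 was also high, thus showed no rise of this list as a set. Single titles, picked after their values were seen, went both ways. Cytoplasmic Polyadenylation Element Binding Protein 3, not called, stood at 9.42 in OF2 and 8.55 in OF4, against at most 8.45 nearshore. Geminin, DNA Replication Inhibitor, not called, stood at 6.52 and 5.93, against at least 7.53 nearshore. The low percentiles therefore do not show that ovary was absent, and a small amount could be hidden. The difference in reproductive state that the labels give stays open as well, untested.

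Lower sterol synthesis nearshore is a hypothesis raised by 4 called titles: both of Cytochrome P450, Family 51, Farnesyl Diphosphate Synthase, and Insulin Induced Gene 2 (-1.20), a title named after its values were seen. The added list of 12 sterol titles had a median of -0.81 and a camera p of 3.39e-05, which is not independent evidence, since the list came from these 4. It was matched on words in the titles, so it can miss members of this route, also called ones, that carry other names. The other 8 titles gave a median of -0.30 and a camera p of 0.185 (0.228 with an estimated correlation), but taking out the called titles weakens the result by construction, so whether the fall reaches beyond them stays open: adjusted over the list alone 6 fell, among them Similar To Insulin Induced Gene 1 Isoform 1 (-1.03), Farnesyl Pyrophosphate Synthase (-0.61) did not pass, and the 1 riser, an isomerase title, had both means under the detection level. The fixed secretory list had a median of 0.013 and a lower quartile of -0.40, which goes against a general fall of its titles. Of its 32 titles, 2 were called lower and 0 higher, and its mean was -0.08. Its lower quartile lay above -0.81, but this decides nothing, since the sterol list came from called falls. Location itself, with its food and reproductive state, stays open and untested.

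Titles of the axoneme, the core of motile cilia and sperm tails, stood high in nearshore NF2 and offshore OF1, and so were not a matter of location. The 27 titles, all also in the fixed testis and sperm list, had a median deviation from the title's median over the 7 animals of 0.30 in NF2 and 0.60 in OF1, above 99.71% and 100% of 10000 random lists matched on level, which goes against a signal change that ignores gene function, but the list was prompted by these very values, and the whole testis and sperm list fixed earlier reached the percentile 99.5 in OF1 and only 34.34 in NF2, so such a change stays open. Sperm or testis material might add such transcripts, but the 29 other testis and sperm titles, with members going both ways, lay at the percentiles 35.04 in NF2 and 32.77 in OF1, which decides nothing. The axoneme percentiles also split by slide row: OF4, in the same row as NF2 and OF1, lay at 95.63, the animals of the other row at 0.41 (NM3), 0.46 (OF2) and 21.49 (OF3), and NF3, with an array in each row, at 10.09. On the whole testis and sperm list OF4 lay at 98.21, above the range of random lists, NM3 at 0.1, OF2 at 1.48, OF3 at 12.79 and NF3 at 11.77. The oocyte titles were high in NF2 and OF1 (98.37 and 99.96) but low in OF4 (0.55). The 2 arrays of NF3, 1 in each row, differed by a median of 0.0985 over all tested probes, which does not single out the axoneme titles. The slide row was not tested as a cause, and it stays open beside ciliated tissue and germ cells. The labels put these animals in no common group that could be tested.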
